A study of Mus musculus with 8 samples.

How the data were processed

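RNA was measured by RNA-seq in c-KIT-high sorted leukemic bone marrow cells of C57BL/6 mice, transformed with the MLL-AF9 fusion oncogene. The cells either carried an intact Ikzf2 gene (WT, 2 libraries) or had lost it (KO, 2 libraries). Per the labels' protocols, frozen marrow was thawed for sorting, RNA was extracted with TRIzol and RNeasy columns, and libraries were made with the TruSeq RNA kit. The series also names 4 chromatin accessibility samples, which were not analysed here. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the replicates came from separate mice. The KO libraries differed in their sex-linked genes, as given below, so they were not technical repeats of the same cells. For the WT libraries this stays open. The p-values therefore measure the spread between these libraries, which may in part be technical.

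The files hold raw counts per gene symbol, 1 file per library, as the authors deposited them. Per the submitters' processing notes, the tools were STAR 2.3.0, HTSeq, Bowtie2 2.2.5, Picard and MACS2, with build mm10. Those notes give no role for each tool. The annotation, strand setting and read filters are not given in the sources used here. Without a stated strand setting, reads of overlapping and antisense genes cannot be told apart. Near-identical copies such as Hspa1a and Hspa1b can lose or share reads, so their counts are uncertain.

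Each deposited file listed 24421 gene symbols, and 5 closing rows of reads assigned to no gene were left out of library sizes and tests. Those rows held 72.2% and 71.7% of all counts in WT replicates 1 and 2, and 72.4% and 69.3% in KO replicates 1 and 2. Reads assigned to no counted feature made up 58.8%, 58.2%, 58.5% and 58.3% of the uniquely aligned reads in the same order. The sources used here do not say where these reads lay. Gene counts came to 19286090 and 18711837 in WT and to 16006081 and 18017545 in KO. At these depths a count of 3 equals 0.156, 0.160, 0.187 and 0.167 CPM, a gene's count scaled by its library's total. The ribosomal precursor gene Rn45s took 0.998%, 1.08%, 1.36% and 0.686% of gene counts. The replicates of a group differed beyond counting noise, with a chi-square per degree of freedom of 84.6 in WT and 115 in KO. Each therefore counted as its own sample, although this value does not tell biological from technical difference.

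Analyses were run in R 4.3.3. Genes were kept by the default filterByExpr rule of edgeR 4.0.16, which left 12623. Counts were scaled with TMM factors, and CPM values below are TMM-normalised. KO was compared with WT by edgeR's quasi-likelihood F-test with robust dispersion moderation, no covariate and Benjamini-Hochberg adjustment at a threshold of 0.05. The SE of a log2 fold change was the fold change's size divided by the square root of F. DESeq2 1.42.0 (Wald test), run on all 16651 genes with a count, and voom in limma 3.58.1, run on the 12623, served as alternatives. "Rose" and "fell" are used below of genes past an adjusted p of 0.05 in the named test. Gene coordinates come from the GRCm38.p6 annotation, the assembly that mm10 names, and 15860 of the 16651 symbols with a count matched it.

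Gene lists, 27 in all with 734 distinct genes, were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. The adjustments of edgeR's p over a list alone, or over the 19 fixed genes alone, were not among the planned tests. They do not correct for the number of lists. Of the list genes 722 were in the files and 584 were tested. The lists cover HOXA-MEIS1 targets, stem and progenitor genes, myeloid transcription factors, primary granules, secondary and tertiary granules, monocytes and lysosomes, antigen presentation, the S and G2/M phases, MYC targets, p53 targets, apoptosis, interferon, NF-kB, cytokine receptors, glycolysis, oxidative phosphorylation, cholesterol synthesis and the Ikaros family with NuRD subunits. Further lists hold markers of erythroid, B, T and NK, megakaryocyte, mast and granulocyte-lineage, and stromal cells, immediate early and heat shock genes, and sex-linked genes. Lists with at least 5 tested genes were tested with limma's camera on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, with an estimated correlation and fry as alternatives. Some genes sit in more than 1 list.

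Named genes follow a rule in 3 parts. The first part is 19 genes chosen by name. The second is the called genes of largest change with a mean of at least 5 CPM in the higher group and no overlap between the groups, predicted and unnamed genes left out, or, with fewer than 10 such genes, the 5 per direction with the smallest unadjusted p. The third is the called members of each list with the smallest adjusted p, or, where a list had none, its 2 members of highest mean CPM. As edgeR called 0 genes, the fallbacks applied. Other genes named below, among them the list members called by DESeq2, were chosen after their values were seen. Some genes that the rule names are not reported here. The DESeq2 fits with libraries left out were also chosen after the data were seen.

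The fits were tested on simulated counts for 12623 genes at the estimated spread. edgeR recovered 8% of 2-fold, 68% of 4-fold, 100% of 8-fold and 96% of 16-fold changes, with 16 false calls among 12423 unchanged genes. On the real counts edgeR called 0 genes, with Ikzf2, 14.8-fold lower in KO, at an adjusted p of 0.332. The simulated shares are therefore not its power in these libraries. DESeq2 recovered 18%, 94%, 100% and 100%, with 79 false calls. These shares were 9, 47, 50 and 50 of 50 changed genes per fold. For edgeR they were 4, 34, 50 and 48. The false share of all simulated calls was thus above the adjusted p threshold for both tools, and larger for DESeq2. Genes said below to have risen or fallen by DESeq2 can therefore include more false calls than their adjusted p states. With no simulated list changed, camera called 0 of 25 lists. Genes were simulated independently of each other, so this does not test the preset correlation on lists whose members vary together. In the data the estimated correlation of a list ran from -0.10 (erythroid) to 0.90 (immediate early and heat shock). It was 0.59 for secondary and tertiary granule genes. With the members of a list doubled, camera called that list with the preset correlation (adjusted p = 5.83e-13) but not with an estimated correlation (adjusted p = 0.862). The estimated correlation thus missed a simulated shift of independent genes, so a list lost under it need not have members that vary together. Alternatives tried were other scaling factors, other low-count filters, other tools, other thresholds, a replicate-number block and each library left out in turn.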

Results

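Expression was measured in sorted leukemic cells driven by MLL-AF9, a fusion oncogene found in acute leukemia, with 2 libraries from Ikzf2 WT and 2 from Ikzf2 KO cells. Ikzf2 encodes Helios, a zinc finger transcription factor of the Ikaros family, and the sort took cells high in c-KIT, a receptor of immature blood cells. Gene counts came to 19286090 and 18711837 in the WT libraries and 16006081 and 18017545 in the KO libraries. The KO replicate 1 library differed from the other 3 in its sex-linked genes: Xist, the X-inactivation RNA, stood at 833 CPM there and at 0.60, 0.48 and 0.35 CPM in WT replicates 1 and 2 and KO replicate 2. The Y-linked gene Ddx3y had 0.062 CPM in KO replicate 1 and 110, 102 and 70.1 CPM in the others. The first principal component of log2 CPM held 46.9% of the variance and separated the genotypes. The next held 33.9% and separated the replicate numbers. The highest correlation of log2 CPM between libraries, 0.950, lay across the genotypes, between WT replicate 2 and KO replicate 2. It was 0.939 between the WT libraries and 0.940 between the KO libraries.

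The targeted gene was examined first. Ikzf2 (chromosome 1, 69531207 to 69687351) had 283 and 271 CPM in the WT libraries and 10.9 and 26.5 CPM in the KO libraries, from raw counts of 5668, 5108, 176 and 451. Its log2 fold change was -3.89 (SE 0.48, n = 2 per group), a 14.8-fold lower level. Ikzf2 fell by edgeR's quasi-likelihood test over the 19 fixed genes alone (adjusted p = 0.00323) and by DESeq2 over all genes (adjusted p = 1.13e-13). The adjusted p of edgeR over all 12623 genes was 0.332. It was 0.0176 without WT replicate 1, 0.0105 without WT replicate 2, 0.700 without KO replicate 1 and 0.285 without KO replicate 2, where the lone library left in a group was assumed to vary like the other group. Over the other edgeR and voom settings it ran from 0.0695 to 0.397. The fold change was -4.67 without KO replicate 2. The labels do not state which exons were deleted, so the remaining counts can include exons outside the deletion.

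**Figure D1:**
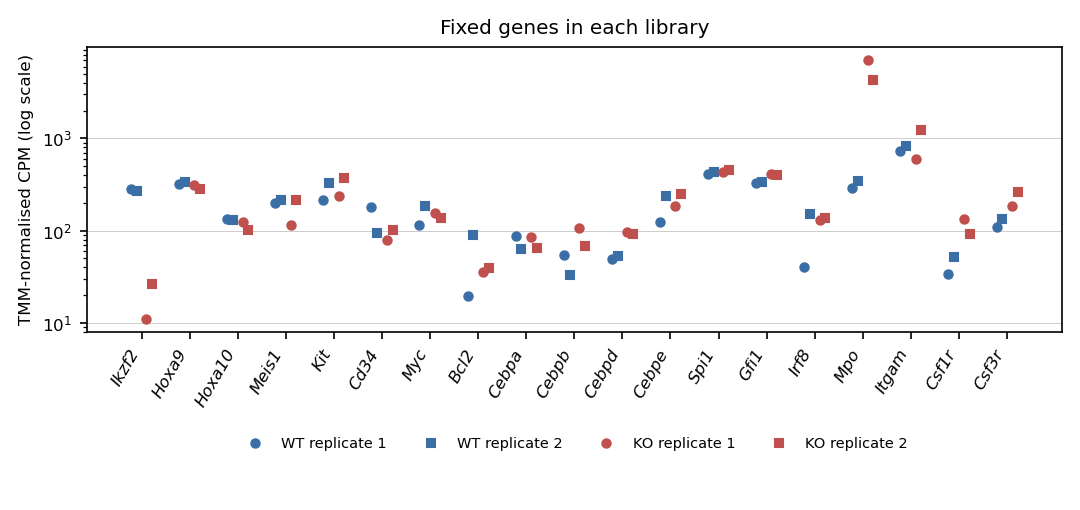
TMM-normalised CPM (log axis) of the 19 fixed genes in each library, with WT in blue and KO in red, circles for replicate 1 and squares for replicate 2. Ikzf2 lies at 283 and 271 CPM in WT and 10.9 and 26.5 CPM in KO, and Mpo at 286 and 343 CPM in WT and 7074 and 4311 CPM in KO.

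The comparison of KO with WT addressed whether loss of Ikzf2 alters the self-renewal and myeloid differentiation programs of these cells, as the series title frames it. Of the lists fixed beforehand, secondary and tertiary granule genes had the highest median log2 fold change, 1.62, with 33 of 36 members above 0 (camera adjusted p = 1.76e-12; adjusted p = 0.611 with an estimated correlation). Mpo, the myeloperoxidase of primary granules (chromosome 11, 87793784 to 87804412), rose by DESeq2 from 286 and 343 CPM to 7074 and 4311 CPM (log2 fold change 4.18 by edgeR, SE 0.37, DESeq2 adjusted p = 1.54e-30). Cebpd, a C/EBP transcription factor, rose from 48.8 and 53.3 CPM to 97.5 and 91.8 CPM. Csf1r, the M-CSF receptor, rose from 34.0 and 51.6 CPM to 135 and 90.8 CPM. Both also passed edgeR over the 19 fixed genes alone (adjusted p = 0.0278 for each), as did Ikzf2 and Mpo (adjusted p = 0.00109). With a library left out, DESeq2 called Mpo in 4 of 4 fits and Cebpd in 0 (adjusted p = 0.9998 without WT replicate 1, 0.547 without WT replicate 2, 0.382 without KO replicate 1 and 0.149 without KO replicate 2), while the log2 fold change of Cebpd by edgeR ran from 0.83 to 0.97 in these fits. It lost Csf1r without WT replicate 1 (adjusted p = 0.565) and KO replicate 1 (0.366).

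Over all genes, edgeR called 0 of 12623 genes at an adjusted p of 0.05, with 968 at an unadjusted p under 0.05, against 631 by chance, and a lowest adjusted p of 0.207. DESeq2 called 352 genes, 209 higher and 143 lower in KO, and voom called 0, with 935 at an unadjusted p under 0.05. Both KO libraries lay on the same side of both WT libraries in 37.2% of genes, against 33.3% by chance. Among the 5 genes per direction with the smallest edgeR p, 0 of which passed edgeR over all genes, Wfdc21, a gene of the whey acidic protein domain family, had 1.30 and 1.01 CPM in WT and 43.1 and 63.6 CPM in KO (log2 fold change 5.52, SE 0.38). Prom1, which encodes the stem cell surface antigen CD133, had 8.65 and 10.2 CPM in WT and 62.4 and 90.9 CPM in KO. Pag1, a membrane adaptor of Src family kinases, had a log2 fold change of 2.26 (SE 0.23), and Ifitm3, an interferon-induced membrane protein, of 3.31 (SE 0.35). On the lower side, Tespa1 went from 91.1 and 132 CPM to 13.5 and 14.6 CPM (log2 fold change -2.98, SE 0.27). Inppl1, which encodes the lipid phosphatase SHIP2, had -2.40 (SE 0.28), the calpain Capn2 -2.44 (SE 0.31) and the receptor Erbb3 -3.19 (SE 0.44). These 10 genes, Ikzf2 and Mpo included, all passed DESeq2, with the highest adjusted p, 2.78e-08, at Capn2, and DESeq2 called each of them in 4 of 4 fits with a library left out. Leaving out WT replicate 1 or 2 raised edgeR's calls to 50 and 156, where the lone library left was assumed to vary like the KO libraries, and leaving out KO replicate 1 or 2 gave 0. DESeq2 called 162 genes without WT replicate 1 (86 higher, 76 lower) and 178 without KO replicate 1 (110 higher, 68 lower), of which 98 and 113 were among the 352. It called 390 without WT replicate 2 and 384 without KO replicate 2 (148 higher, 236 lower), of which 163 and 176 were among the 352. Of 51 named genes that DESeq2 called, 21 were called in 4 of 4 such fits. Of the other 30, the edgeR log2 fold change kept its sign in each such fit in 29 and stayed within 1.5-fold of its value over all libraries in 14.

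Genes of neutrophil granules stood above WT as a group. Of 36 tested secondary and tertiary granule and mature neutrophil genes, 33 had a fold change above 0, and 20 were higher in both KO libraries than in both WT libraries, with a median log2 fold change of 1.62. Chil3 had 322 and 1766 CPM in WT and 8449 and 10375 CPM in KO, and Ngp, a secondary granule protein, 432 and 1696 CPM and 3937 and 7844 CPM. DESeq2 called 10 members, among them Chil3, Ngp, S100a8, S100a9 and Lcn2, as higher, 0 passed edgeR over all genes, and Il1r2, Trem1 and Wfdc21 passed edgeR adjusted over the list alone. S100a8, a calcium-binding protein of neutrophils, went from 78.2 and 389 CPM to 1680 and 2520 CPM. The genes Camp and Ltf, of cathelicidin and lactoferrin, had log2 fold changes of 3.48 (SE 0.99) and 3.03 (SE 1.07) and passed neither test. DESeq2 called Wfdc21 and Trem1 in 4 of 4 fits with a library left out and lost Il1r2 without KO replicate 2 (adjusted p = 0.0765). Without KO replicate 1 or 2 it lost Chil3 (adjusted p = 0.709 and 0.545), Ngp (0.683 and 0.776), S100a8 (0.591 and 0.564) and S100a9 (0.932 and 0.781), and without WT replicate 1 or KO replicate 2 it lost Lcn2 (0.0976 and 0.174). Without WT replicates 1 and 2 the fold change was 2.42 and 4.88 for Chil3, 1.80 and 3.78 for Ngp, 2.43 and 4.76 for S100a8, 1.90 and 4.62 for S100a9, 2.67 and 5.51 for Camp and 2.22 and 5.13 for Ltf. Without KO replicate 2 it was 2.04 for Ltf, 1.34 for Lcn2 and 2.11 for Il1r2. The list passed camera (adjusted p = 1.76e-12; adjusted p = 0.611 with an estimated correlation). The median of the list's log2 CPM differences, 2.10 over all libraries, was 0.74 without WT replicate 1 and 3.25 without WT replicate 2, and it was 2.74 within replicate number 1 and 0.96 within replicate number 2. The list was also higher in replicate 2 than in replicate 1, in 34 of 36 cases within WT (median 2.33) and 27 of 36 within KO (median 0.70).

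Of 19 tested primary granule genes, 17 were above 0, with a median of 0.79, and 10 were higher in both KO libraries than in both WT libraries. Mpo, the neutrophil elastase gene Elane, Prtn3, Lyz2 and Cst7 rose by DESeq2 and passed edgeR adjusted over the list alone, while 0 passed edgeR over all genes. Elane went from 1143 and 732 CPM to 10330 and 4912 CPM (log2 fold change 3.02, SE 0.48). Prtn3, the gene of proteinase 3, had a log2 fold change of 1.58 (SE 0.42), and Lyz2, a lysozyme gene, of 1.82 (SE 0.31). DESeq2 called Mpo, Elane and Lyz2 in 4 of 4 fits with a library left out, and the fold change of Elane was 2.39 without KO replicate 1. It lost Prtn3 without WT replicate 2 (adjusted p = 0.241) and KO replicate 1 (0.283), and Cst7 without WT replicate 1 (0.280) and KO replicate 1 (0.416). The list passed camera (adjusted p = 2.47e-07; adjusted p = 0.611 with an estimated correlation), and the median difference was 1.0004 within replicate number 1 and 0.83 within replicate number 2.

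Monocyte, macrophage and lysosome genes were above 0 in 27 of 39 cases, with a median of 0.48. F13a1, the factor XIII subunit made by monocytes, had 25.5 and 14.6 CPM in WT and 232 and 154 CPM in KO (log2 fold change 3.27, SE 0.38). F13a1, Tlr4, Tlr2, Cd300lf, Mpeg1, Clec4a2 and Csf1r rose by DESeq2 and passed edgeR adjusted over the list alone, and 0 passed edgeR over all genes. The most abundant members, Ctsb and Lamp1, had log2 fold changes of 0.34 (SE 0.28) and 0.02 (SE 0.21), and that of Lamp1 was -0.04 with library sizes alone as scaling, while that of Ctsb was 0.079 without WT replicate 1. The list passed camera (adjusted p = 4.54e-04; adjusted p = 0.676 with an estimated correlation), but not without KO replicate 1 (adjusted p = 0.150), the library in which dendritic cell genes were also highest, as given with the antigen presentation genes. The median of its log2 CPM differences, 0.41 over all libraries, was 0.19 without KO replicate 1, 1.09 without KO replicate 2 and 0.84 without WT replicate 2. Within replicate numbers 1 and 2 it was 0.73 and 0.11. DESeq2 called F13a1 and Tlr4 in 4 of 4 fits with a library left out. Of the others it lost Cd300lf without WT replicate 1 (adjusted p = 0.148), Mpeg1 and Csf1r without WT replicate 1 (0.443 and 0.565) or KO replicate 1 (0.189 and 0.366), and Tlr2 without WT replicate 1 (0.593), KO replicate 1 (0.472) or KO replicate 2 (0.0562). Clec4a2 was lost in each of the 4, at 0.896 and 0.0836 without WT replicates 1 and 2 and 0.194 and 0.0624 without KO replicates 1 and 2.

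Of 28 myeloid differentiation transcription factors, 22 were above 0, with a median of 0.75. Id2, an inhibitor of helix-loop-helix factors, rose by DESeq2 from 39.7 and 38.6 CPM to 169 and 127 CPM (log2 fold change 1.92, SE 0.23), as did Cebpd, and Id2 passed edgeR adjusted over the list alone, with 0 members past edgeR over all genes. With a library left out, DESeq2 called Id2 in 4 of 4 fits and Cebpd in 0, with the values given above. The other fixed regulators passed neither test: Cebpb had 0.99 (SE 0.35), Irf8 0.48 (SE 0.61), Cebpe 0.28 (SE 0.37), Gfi1 0.27 (SE 0.20) and Spi1 0.07 (SE 0.21). Cebpa was at 86.6 and 62.8 CPM in WT and 85.3 and 64.1 CPM in KO. The receptors Csf3r and Itgam had 0.87 (SE 0.26) and 0.24 (SE 0.38). The list passed camera (adjusted p = 0.00193; adjusted p = 0.611 with an estimated correlation), but not without WT replicate 1 (adjusted p = 0.163) or KO replicate 2 (adjusted p = 0.258). In log2 CPM differences its median, 0.63 over all libraries, was 0.13 without WT replicate 1 and 0.11 without KO replicate 2, and 0.53 and 0.79 within replicate numbers 1 and 2. Its most abundant members, the immediate early genes Jun and Fos, were also higher in replicate 2 of both groups, at 303 and 1002 CPM for Jun in WT and 383 and 2832 CPM in KO.

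In the HOXA-MEIS1 program, which MLL fusions sustain, 22 of 26 tested genes were below 0, with a median of -0.33, and 0 passed edgeR, adjusted over the list alone or over all genes, or DESeq2. Hoxa9 was at 318 and 334 CPM in WT and 312 and 280 CPM in KO (log2 fold change -0.14, SE 0.21). Hoxa10 had -0.23 (SE 0.20), Meis1 -0.33 (SE 0.34), Bcl2 -0.55 (SE 0.70), Lmo2 -0.02 (SE 0.26) and Myb 0.04 (SE 0.22), which was -0.025 with library sizes alone as scaling. Hoxa5, at 172 and 146 CPM in WT and 90.9 and 93.9 CPM in KO, had -0.78 (SE 0.20). The list did not pass camera (adjusted p = 0.0555). It passed without KO replicate 2 (adjusted p = 0.0125), but not without WT replicate 1 (0.149), WT replicate 2 (0.166) or KO replicate 1 (0.703). The median of its log2 CPM differences, -0.26 over all libraries, was -0.043 without KO replicate 1 and -0.45 without WT replicate 1.

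Of 16 tested stem and progenitor genes 11 were below 0, with a median of -0.37. Gata2, a transcription factor of blood stem and progenitor cells, fell by DESeq2 from 74.4 and 234 CPM to 14.0 and 49.3 CPM. Prdm16 rose by DESeq2 from 1 and 0 counts to 28 and 32 counts and passed edgeR adjusted over the list alone, while 0 members passed edgeR over all genes. Gata2 lost its DESeq2 call without WT replicate 2 (adjusted p = 0.787) and KO replicate 1 (0.375). Prdm16 lost its call without WT replicate 1 (0.186) and WT replicate 2 (0.285) and had no adjusted p without either KO library. The fold change of Gata2, -2.28, was -1.22 without WT replicate 2 and -3.46 without KO replicate 2, and that of Cd34 was -0.085 without WT replicate 1 and -0.99 without WT replicate 2. Cd34 had a log2 fold change of -0.62 (SE 0.35), Lyl1 of -0.06 (SE 0.21) and Kit, the sorted receptor, of 0.17 (SE 0.34), with 216 and 330 CPM in WT and 236 and 376 CPM in KO. The list did not pass camera (adjusted p = 0.198). It passed without KO replicate 2 (adjusted p = 0.0440), and camera's direction turned without KO replicate 1 (adjusted p = 0.582). The median of its log2 CPM differences, -0.45 over all libraries, stayed below 0, at -0.13 and -0.18 without WT replicates 1 and 2 and -0.16 and -0.82 without KO replicates 1 and 2.

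**Figure D2:**
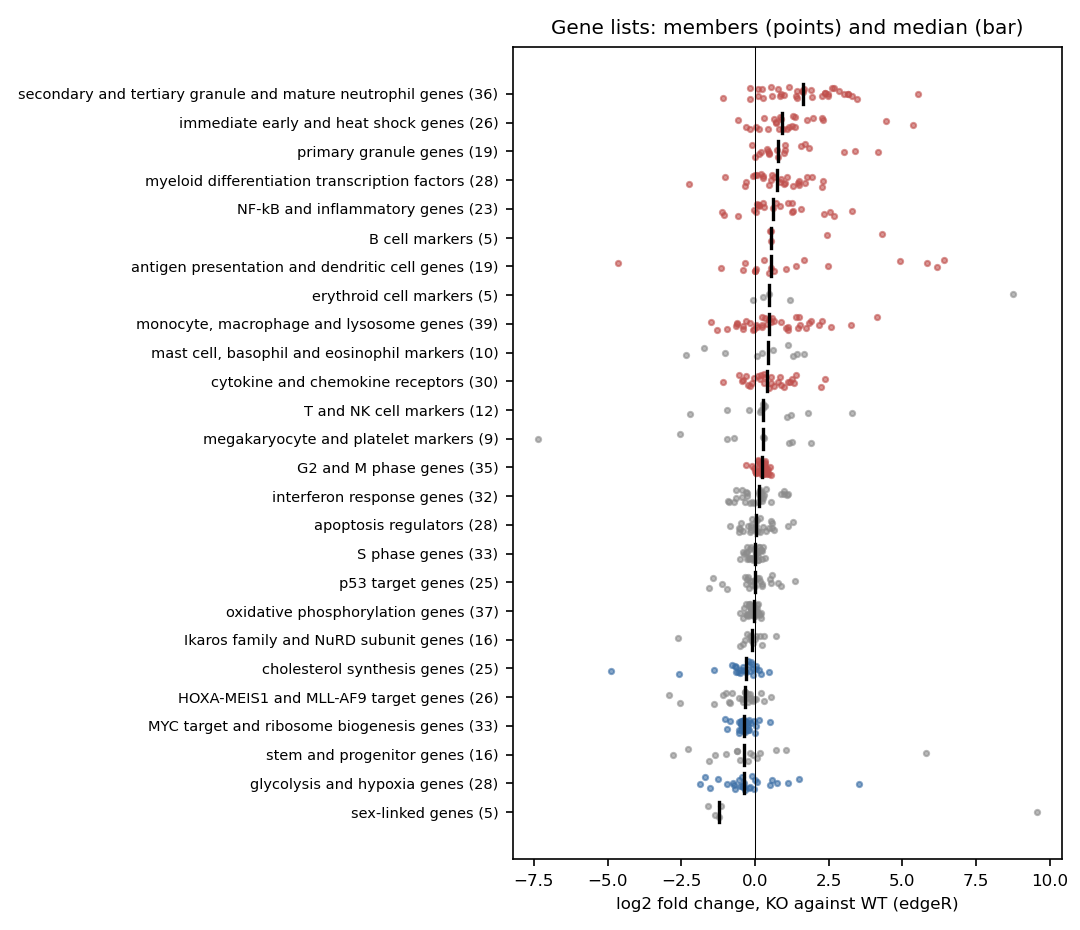
edgeR log2 fold change (KO against WT) of the tested members of each list (points) with the list's median (bar), and the number tested in brackets. Lists past camera at an adjusted p of 0.05 with the preset correlation are red when higher and blue when lower in KO, and 0 lists passed with an estimated correlation. The secondary and tertiary granule list has the highest median, 1.62.

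MYC target and ribosome biogenesis genes were below 0 in 30 of 33 cases, with a median of -0.36, and 22 were lower in both KO libraries than in both WT libraries. Ncl, which encodes the nucleolar protein nucleolin, had -0.30 (SE 0.22), Ldha, the lactate dehydrogenase A gene, -0.36 (SE 0.22) and Myc itself -0.05 (SE 0.29). The list passed camera (adjusted p = 4.07e-05; adjusted p = 0.611 with an estimated correlation), with a median difference of -0.41 and -0.26 within replicate numbers 1 and 2. Of its members 0 passed edgeR, adjusted over the list alone or over all genes, or DESeq2.

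Glycolysis and hypoxia genes were below 0 in 21 of 28 cases, with a median of -0.37 (camera adjusted p = 0.00639; adjusted p = 0.676 with an estimated correlation). Aldoc, an aldolase, and Egln3, a prolyl hydroxylase induced by hypoxia, fell by DESeq2 and passed edgeR adjusted over the list alone, with log2 fold changes of -1.86 (SE 0.37) and -1.53 (SE 0.30). DESeq2 called 2 members as higher and 3 as lower, and 0 passed edgeR over all genes. Ldhb rose by DESeq2 from 0.55 and 5.62 CPM to 35.6 and 36.4 CPM. Pkm had -0.55 (SE 0.23), and Gpi1 was at 1855 and 1841 CPM in WT and 1493 and 2192 CPM in KO. Cholesterol synthesis genes were below 0 in 20 of 25 cases, with a median of -0.30 (camera adjusted p = 0.0226; adjusted p = 0.691 with an estimated correlation). Of its members 0 passed edgeR, adjusted over the list alone or over all genes, and DESeq2 called 2 as lower. Srebf2, a transcription factor of sterol synthesis, had -0.15 (SE 0.25). Within replicate numbers 1 and 2 the median difference was -0.55 and -0.20 for glycolysis and -0.55 and -0.066 for cholesterol synthesis. The glycolysis list lost its call without WT replicate 1 (adjusted p = 0.0597), WT replicate 2 (0.0625) or KO replicate 1 (0.272). The cholesterol list lost its call without WT replicate 1 (adjusted p = 0.859), KO replicate 1 (0.0590) or KO replicate 2 (0.349). In log2 CPM differences its median, -0.25 over all libraries, turned to 0.056 without WT replicate 1, and was -0.60 without WT replicate 2 and -0.14 without KO replicate 2. DESeq2 lost Aldoc without WT replicate 1 (adjusted p = 0.297), WT replicate 2 (0.167) or KO replicate 1 (0.130), Egln3 without WT replicate 1 (0.565) or KO replicate 1 (0.112), and Ldhb without KO replicate 1 (0.134) or KO replicate 2 (0.0792). The fold change of Ldhb, 3.55, was 2.68 and 6.03 without WT replicates 1 and 2.

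In the cell cycle lists, 32 of 35 G2 and M phase genes were above 0, with a median of 0.25, while the 33 S phase genes had a median of 0.002. Mki67 and Top2a, the most abundant G2 and M phase genes, had log2 fold changes of 0.25 (SE 0.40) and -0.10 (SE 0.33), and 0 members of either list passed edgeR, adjusted over the list alone or over all genes, or DESeq2. The G2 and M list passed camera (adjusted p = 0.00193; adjusted p = 0.676 with an estimated correlation), but not without WT replicate 1 (adjusted p = 0.0597), WT replicate 2 (0.0532) or KO replicate 2 (0.254). Its median difference, 0.24 over all libraries, was 0.15 without KO replicate 2 and 0.18 and 0.34 within replicate numbers 1 and 2. The S phase list did not pass (adjusted p = 0.987), and it passed on the lower side without WT replicate 2 (adjusted p = 0.0435), where its median difference was -0.23.

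Antigen presentation and dendritic cell genes were above 0 in 14 of 19 cases, with a median of 0.54, and the class II genes carried the highest fold changes. Cd74, the class II invariant chain, was at 2.45 and 7.96 CPM in WT and at 821 and 58.6 CPM in KO replicates 1 and 2. Cd74, H2-Aa, H2-Eb1 and their activator Ciita rose by DESeq2, and Tap2, a peptide transporter of class I presentation, fell from 539 and 431 CPM to 184 and 256 CPM. Cd74, Ciita, H2-Eb1 and Tap2 passed edgeR adjusted over the list alone, and 0 members passed edgeR over all genes. The fold change of Cd74 was 6.40 over all libraries and 3.50 without KO replicate 1, where H2-Eb1 went from 6.18 to 2.96, H2-Aa from 5.84 to 2.70 and Ciita from 4.92 to 3.72. DESeq2 lost Cd74 without WT replicate 1 (adjusted p = 0.294), Ciita without KO replicate 1 (0.631), H2-Eb1 without WT replicates 1 and 2 (0.429 and 0.139), H2-Aa without WT replicates 1 and 2 and KO replicate 1 (0.611, 0.0941 and 0.150) and Tap2 without the same 3 libraries (0.779, 0.143 and 0.189). The class I genes B2m and H2-K1 had 0.65 (SE 0.35) and 0.31 (SE 0.24), and 0.11 and 0.13 without KO replicate 1. Of 10 dendritic cell genes of the list, 8 had their highest CPM in KO replicate 1, such as Cd209a with 0, 1, 99 and 1 counts in WT replicates 1 and 2 and KO replicates 1 and 2. The list passed camera (adjusted p = 0.0165; adjusted p = 0.683 with an estimated correlation), but not without KO replicate 1 (adjusted p = 0.582). The median of its log2 CPM differences, 0.42 over all libraries, went below 0, to -0.041, without KO replicate 1. It was 1.85 without KO replicate 2, 0.92 and 0.88 without WT replicates 1 and 2, and 1.13 and 0.031 within replicate numbers 1 and 2.

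Of 5 tested B cell markers 5 were above 0, with a median of 0.56, and Cd79b and Cd72, genes of B cell surface proteins, had 0.55 (SE 0.32) and 0.56 (SE 0.51). The median WT level of the tested markers was only 0.70 CPM. Too few of them passed the filter at 5 CPM in 2 libraries for camera to be run there. Of these markers 0 passed edgeR, adjusted over the list alone or over all genes, or DESeq2. That list passed camera (adjusted p = 0.00193; adjusted p = 0.611 with an estimated correlation), but not without WT replicate 1 (adjusted p = 0.0597) or KO replicate 1 (0.150), and its median difference, 0.54 over all libraries, was 0.30 without KO replicate 1 and 0.72 and 0.50 within replicate numbers 1 and 2. Cd79b and Cd72 had 0.28 and 0.20 without KO replicate 1.

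Cytokine and chemokine receptors were above 0 in 21 of 30 cases, with a median of 0.40 (camera adjusted p = 0.00193; adjusted p = 0.611 with an estimated correlation). Csf1r, Il6ra and Tnfrsf1b rose by DESeq2, with log2 fold changes of 1.40 (SE 0.32), 1.18 (SE 0.26) and 1.12 (SE 0.26), while Ifngr1 and Csf2ra, the most abundant, had -0.03 (SE 0.28) and -0.30 (SE 0.29). Of these receptors 0 passed edgeR, adjusted over the list alone or over all genes. Il6ra was lost by DESeq2 in each of the 4 fits with a library left out (adjusted p = 0.786, 0.196, 0.0542 and 0.326 without WT replicates 1 and 2 and KO replicates 1 and 2), and Tnfrsf1b in 3 of them (0.296, 0.523 and 0.381 in the same order). Csf1r was lost without WT replicate 1 (0.565) and KO replicate 1 (0.366). The median difference of the receptors was 0.50 and 0.28 within replicate numbers 1 and 2.

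NF-kB and inflammatory genes were above 0 in 19 of 23 cases, with a median of 0.61 (camera adjusted p = 0.0471; adjusted p = 0.691 with an estimated correlation). Nfkbia and Nfkb1 had 0.87 (SE 0.22) and 0.06 (SE 0.36), and 0 members passed edgeR, adjusted over the list alone or over all genes, while DESeq2 called 2 as higher and 1 as lower. In log2 CPM differences its median, 0.27 over all libraries, went below 0, to -0.039, without WT replicate 1, and was 0.90 without WT replicate 2, 0.98 without KO replicate 1 and 0.12 without KO replicate 2. It was 0.20 and 0.53 within replicate numbers 1 and 2. The NF-kB list was also higher in replicate 2 than in replicate 1, in 19 of 23 cases within WT (median 0.91) and 18 of 23 within KO (median 0.79). That list lost its call with DESeq2 size factors (adjusted p = 0.0525), without WT replicate 1 (0.392) and without KO replicate 2 (0.518). Immediate early and heat shock genes were above 0 in 23 of 26 cases, with a median of 0.90 (camera adjusted p = 0.00649; adjusted p = 0.691 with an estimated correlation). Jun and Fos had log2 fold changes of 1.30 (SE 1.04) and 1.10 (SE 1.06), which turned to -0.77 and -0.52 without KO replicate 2. Hspa1b, a heat shock protein gene, rose by DESeq2, but not without WT replicate 1 (adjusted p = 0.674), WT replicate 2 (0.0865) or KO replicate 2 (0.436), where its fold change went from 5.37 to 2.68, and 0 members passed edgeR, adjusted over the list alone or over all genes. They were also higher in replicate 2 than in replicate 1 in 25 of 26 cases within WT and 26 of 26 within KO, and the KO minus WT median was 0.39 and 1.13 within replicate numbers 1 and 2. That list lost its call without WT replicate 1 (adjusted p = 0.690), and its direction turned without KO replicate 2 (adjusted p = 0.349). In log2 CPM differences its median, 0.73 over all libraries, was 0.084 and 1.34 without WT replicates 1 and 2 and 1.58 and -0.12 without KO replicates 1 and 2.

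The remaining lists did not pass camera over the 4 libraries. Adjusted p was 0.725 for p53 targets, 0.591 for apoptosis regulators, 0.790 for interferon response genes, 0.239 for oxidative phosphorylation genes and 0.239 for the Ikaros family and NuRD subunits. For apoptosis regulators the camera direction was above 0, while the median log2 CPM difference was -0.12. Among these genes Bcl2l11, which encodes the cell death activator BIM, and Tnfrsf1b rose by DESeq2, with 19.5 and 22.2 CPM in WT and 57.6 and 43.5 CPM in KO for Bcl2l11. Chd3, a NuRD helicase, fell by DESeq2 from 219 and 251 CPM to 16.8 and 59.7 CPM. DESeq2 called Chd3 in 4 of 4 fits with a library left out, with fold changes from -3.80 to -1.97 by edgeR, but lost Bcl2l11 and Tnfrsf1b without WT replicate 1 (adjusted p = 0.567 and 0.296), WT replicate 2 (0.182 and 0.523) and KO replicate 1 (0.377 and 0.381). Over these 5 lists 0 genes passed edgeR, adjusted over the list alone or over all genes.

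Of the markers of other cells, adjusted p by camera was 0.0804 for erythroid cells, 0.0576 for T and NK cells, 0.971 for megakaryocytes and 0.0982 for mast cells, basophils and eosinophils. The megakaryocyte list had a median of 0.26 but a camera direction below 0. The sex-linked list had an adjusted p of 0.181. In these 5 lists 0 genes passed edgeR, adjusted over the list alone or over all genes, and DESeq2 called Xist and 1 erythroid gene. Xist was lost without WT replicate 1 (adjusted p = 0.459) and WT replicate 2 (0.367). Without KO replicate 1 it had no adjusted p and its edgeR log2 fold change was -0.60. Only 4 stromal and endothelial markers were tested, too few for camera, and of these Vcam1, an adhesion molecule, rose by DESeq2 from 9.60 and 21.6 CPM to 136 and 87.8 CPM and Pdgfrb fell from 114 and 44.2 CPM to 6.12 and 17.5 CPM. Both passed edgeR adjusted over the list alone and 0 passed over all genes. DESeq2 called Vcam1 in 4 of 4 fits with a library left out and lost Pdgfrb without WT replicate 1 (adjusted p = 0.271) and KO replicate 1 (0.0514). In these fits the edgeR fold change ran from 2.37 to 3.55 for Vcam1 and -3.69 to -1.90 for Pdgfrb. Some list calls arose with a library left out: oxidative phosphorylation on the lower side without WT replicate 2 (adjusted p = 0.0400) or KO replicate 1 (0.00188), T and NK cells without WT replicate 2 (0.00151), erythroid cells without KO replicate 1 (0.00742), and the Ikaros family and NuRD subunits (0.0273) and sex-linked genes (0.0440) without KO replicate 2.

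**Figure D3:**
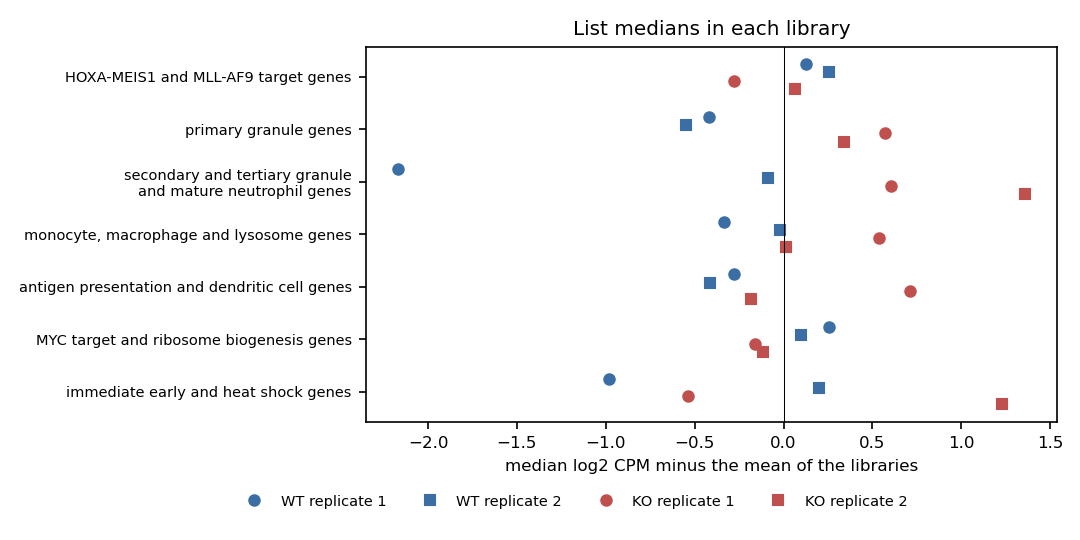
Median over list members of log2 CPM minus the gene's mean over the 4 libraries, for 7 lists, with WT in blue and KO in red, circles for replicate 1 and squares for replicate 2. The secondary and tertiary granule genes lie at -2.17 and -0.09 in WT and 0.60 and 1.36 in KO. The immediate early and heat shock genes lie at -0.98 and 0.20 in WT and -0.54 and 1.23 in KO.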

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

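The DESeq2 fits with libraries left out or with the block and the edgeR fit with bias-adjusted deviances were chosen after the data were seen, and the other settings before. Every setting run on all or 3 libraries kept the lower level of Ikzf2, from -4.67 to -3.39. edgeR's count of 0 genes was kept with other scaling factors, voom, bias-adjusted deviances, robust moderation off and a filter at 5 CPM in 2 libraries. Adjusted p thresholds of 0.01 and 0.1 had to give 0 too, as the lowest adjusted p by edgeR was 0.207. So did a test against a fold of 1.5, which is stricter than the main test. Without a low-count filter the count became 4 (3 higher, 1 lower, namely Mpo, Prom1, Wfdc21 and Tespa1). With DESeq2 it became 352 (209 higher, 143 lower). DESeq2 did not use edgeR's filter and gave 13422 genes an adjusted p, against 12623 in edgeR. Without a low-count filter edgeR ran on the same 16651 genes as DESeq2 and called 4, so leaving out the filter did not by itself bring the larger count. The genes over which p was adjusted still differed between the tools. Of DESeq2's 352 calls, 341 were of genes that edgeR tested with its filter. With the replicate number as a block edgeR's count became 11 (8 higher, 3 lower). Among these were Mpo, Prom1, Wfdc21, Tespa1, F13a1, Trem1, Gata2 and Pcdh7. The deviations of equal numbers correlated at 0.19 across genes, and as the labels do not say that a number marks a shared mouse or day, the numbers do not count as pairs. The block also brought the HOXA-MEIS1 list (adjusted p = 0.0289) and the erythroid list (0.0397) past camera, for 15 lists. With each library left out, edgeR's count ran from 0 to 156, with 0 to 100 higher and 0 to 56 lower. DESeq2's ran from 162 to 390, with 86 to 285 higher and 68 to 236 lower. Of the 13 lists past camera, 0 remained with an estimated correlation and 0 with fry (lowest adjusted p 0.141), and 6 to 14 passed with a library left out. Fewer libraries change both the filter and the spread, and beyond that the cause was not tested. The estimated correlation also took the cytokine receptor list, whose estimate was -0.024, from an unadjusted camera p of 5.7e-04 to 0.060. Calls lost with it therefore do not measure how far list members varied together. No scaling moved the median log2 fold change of all genes by over 0.1; the largest shift was to -0.07, with library sizes alone.

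Of the named genes' values, 45 changed sign, 1191 kept sign and side, and 102 passed the threshold only in an alternative. As edgeR called 0 genes over all libraries, a named gene had no call to lose. Sign changes outside the left-out libraries concerned values near 0. Cebpa became 0.01 with DESeq2 size factors (0.012), without a low-count filter (0.0097) and by DESeq2 (0.0093), and 0.0056 with the 5 CPM filter, 0.0021 with voom and 0.0037 with the block. Gpi1 became 0.0087, 0.0077 and 0.0076 with DESeq2 size factors, without a filter and by DESeq2. Lmo2 became 0.0014 with voom and 0.0020 with the block. Myb and Lamp1 became -0.025 and -0.037 with library sizes alone. With each library left out, log2 fold changes ran from -0.86 to 0.055 for Meis1, -0.21 to 0.52 for Kit, -0.35 to 0.35 for Myc, -1.26 to 0.96 for Bcl2, -0.22 to 0.25 for Cebpa, -0.11 to 0.84 for Cebpe, -0.18 to 1.75 for Irf8, -0.37 to 0.67 for Itgam, -0.030 to 0.12 for Myb, -0.25 to 0.27 for Lmo2, -0.14 to 0.030 for Lyl1, -0.77 to 2.42 for Jun and -0.52 to 2.84 for Fos. They ran from -0.50 to 4.29 for Egr1, -0.035 to 0.10 for Lamp1, -0.40 to 0.70 for Mki67, -0.58 to 0.25 for Top2a, -0.31 to 0.25 for Gpi1, -0.42 to 0.074 for Srebf2, -0.28 to 0.29 for Ifngr1, -0.34 to 0.64 for Nfkb1, -0.60 to 10.57 for Xist and -6.33 to 5.47 for Six4. Without a change of sign, they ran from -0.99 to -0.085 for Cd34, -0.22 to -0.060 for Hoxa9, -0.38 to -0.088 for Hoxa10, 0.64 to 1.40 for Cebpb, 0.037 to 0.12 for Spi1, 0.079 to 0.67 for Ctsb, 0.11 to 1.04 for B2m, 0.13 to 0.48 for H2-K1, -0.64 to -0.024 for Csf2ra, 0.28 to 0.77 for Cd79b, 0.20 to 0.84 for Cd72, -11.75 to -5.58 for Pcdh7 and -10.59 to -0.59 for Ddx3y.

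Of the lists' values, 17 changed direction, 45 lost a call, 13 gained one and 180 did neither. These directions are those of the set test, given here with the median of log2 CPM differences. With fry the test turned for stem and progenitor genes and S phase genes, whose medians, -0.45 and 0.020, do not depend on the test. With library sizes alone it turned for S phase genes, as did the median (-0.044), and for megakaryocyte genes (median 0.18), and with the 5 CPM filter for interferon genes (median 0.098). That filter also brought the HOXA-MEIS1 list (adjusted p = 0.0338) and the stem and progenitor list (0.0159) past camera, and library sizes alone the T and NK list (0.0295). With each library left out, medians stayed below 0 in 2 lists whose test turned, from -0.82 to -0.13 for stem and progenitor genes and -0.26 to -0.011 for the Ikaros family and NuRD. Medians changed sign, with or without a turn of the test, from -0.041 to 1.85 for antigen presentation, -0.039 to 0.98 for NF-kB, -0.60 to 0.056 for cholesterol synthesis, -0.13 to 0.75 for mast cells, -0.23 to 0.19 for S phase, -0.16 to 0.15 for p53 targets, -0.12 to 0.041 for apoptosis, -0.10 to 0.14 for interferon, -0.26 to 0.12 for oxidative phosphorylation, -0.54 to 0.42 for megakaryocytes and -0.12 to 1.58 for immediate early genes. Other medians ran from 0.27 to 1.20 for T and NK cells, 0.29 to 0.91 for erythroid cells and -8.44 to -0.35 for sex-linked genes. Depth limits genes near the floor of 3 counts, such as Prdm16 with 1 and 0 counts in WT. The biological coefficient of variation was 0.37.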

Other observations

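The splits and the tests of explanations in this part, and the genes named first, were chosen after the results were seen. Beyond the lists, Bcl11a, a transcription factor of lymphoid progenitors, rose by DESeq2 from 0.30 and 0.053 CPM in WT to 9.16 and 10.2 CPM in KO (adjusted p = 6.79e-09), and Mgst2, a glutathione transferase of leukotriene synthesis, from 7.30 and 11.7 CPM to 153 and 54.5 CPM (adjusted p = 2.24e-07). DESeq2 called both in 4 of 4 fits with a library left out, where the edgeR log2 fold change ran from 4.99 to 7.33 for Bcl11a and 2.52 to 4.01 for Mgst2. Some genes were high in WT replicate 1 above all. Six4, a gene of the HOXA-MEIS1 list, stood at 76.5 and 0.11 CPM in WT and 9.59 and 0.47 CPM in KO. Pcdh7, a protocadherin, stood at 430 and 22.3 CPM in WT and 0.87 and 0.059 CPM in KO, and Batf3 at 17.0 and 0 CPM in WT. The 3 ways to split the 4 libraries into pairs are too few for a share under 0.05. DESeq2 called 352 genes for the real split, which no other matched (1 of 3), 143 for replicate 1 against 2, the highest of the others, and 17 for the crossed split. edgeR called 0 in each.

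The first pattern is the higher level of mature neutrophil granule genes in the KO libraries. The library with female expression, KO replicate 1, does not account for it alone, since the median log2 difference was 2.01 without that library and 2.10 with it. The median was 0.74 without WT replicate 1 and 3.25 without WT replicate 2, so the low level in WT replicate 1 carried much of the difference. The list also followed the replicate number, with 34 of 36 members higher in WT replicate 2 than in WT replicate 1 (median 2.33) and 27 of 36 in KO (median 0.70), but each group holds 1 library of each number, and the KO minus WT median was at least 0.96 within a number, with 33 and 29 of 36 members higher, which argues against the number as the whole cause. A larger share of KIT-low cells in the KO samples, which the c-KIT-high gate would remove, stays open too, as Kit had a log2 fold change of 0.17 (SE 0.34), within its SE of 0, and -0.21 to 0.52 with a library left out. Loss of Ikzf2 and a difference between individual leukemias also remain open as untested, as the labels name no animals.

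The second pattern is the higher level of immediate early and heat shock genes in replicate 2 of both groups. At least 25 of 26 members were higher in replicate 2 in each group, and the median within WT was 1.27 higher. Both WT libraries carry Ikzf2, so its loss is argued against as the cause of the difference between them, while no value here tests handling. The labels give no sort day, so handling and leukemia cannot be told apart here. Egr1, at 18.4 and 189 CPM in WT and 73.3 and 639 CPM in KO, shows the pattern.

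The third pattern is the high level of class II genes in KO replicate 1 and, to a lesser degree, in KO replicate 2. In KO replicate 1, dendritic cells within the sorted fraction are a candidate source, although the c-KIT-high gate would remove such cells. Of 10 dendritic cell genes fixed beforehand, 8 were highest in that library, among them Cd209a (6.12 CPM), Cd80 (4.33 CPM) and Cd86 (3.09 CPM), while Cd74 stood at 821 CPM. Of a wider list of 13 dendritic and macrophage genes, drawn up after some of their counts had been seen, 11 were highest there, at 9.84 CPM or less. The most abundant of the list, the macrophage gene Adgre1, was lowest there, at 65.0 CPM. It stood at 75.5 and 122 CPM in WT and 97.0 CPM in KO replicate 2. Genes of 1 library vary together and are not independent, so these counts do not decide between such cells and class II expression in the leukemic cells, with loss of Ikzf2 untested. In KO replicate 2 the same cells at a lower share stay open, as the summed count of 50 was set against a WT level that Batf3 in WT replicate 1 dominates, while sex is argued against, since this library has male expression and its class II genes were at least 4.22 times the higher WT value.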
